A study of Mus musculus with 2 samples.

How the data were processed

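RNA of Ly6C-high monocytes from the colon lamina propria was measured on 2 arrays, 1 of WT and 1 of Nlrp6-/- mice, and samples were grouped by the genotype in the labels. The labels do not state how many mice gave each RNA. Per the labels' protocols, RNA was extracted with a column kit for small samples and DNA was removed. Then 10 ng of RNA was amplified to cDNA with a NuGEN whole-transcriptome kit, 3 µg of cDNA was biotinylated, and 3.7 µg was hybridised for 20 h at 48 °C to Affymetrix Mouse Gene 2.1 ST strip arrays. Another protocol field names an Affymetrix kit for labelling instead, and which of them was used could not be settled.

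Per the labels' protocols, the authors computed expression values by robust multiarray average (RMA) with Bioconductor's oligo package in R 2.15.1, and scanned with Gene Atlas software 1.0.4.267. RMA subtracts background, equalises the distributions of the arrays by quantile normalization and summarises the probes of a probe set, so a shift of all transcripts in one array cannot be seen. The deposited table holds log2 RMA levels per array, with medians of 2.87 in WT and 2.84 in Nlrp6-/-, and no ratios, although the labels also mention ratios. Which arrays were normalized together is not given in the sources used here. The direction of every difference is Nlrp6-/- minus WT, with both columns named by genotype.

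Genes were named from the platform annotation supplied with the table. Of 41345 probe sets, 23525 had 1 gene symbol, 1810 had several and 16010 had none. No gene was named from a probe set with several. Of the single-symbol probe sets, 23328 had a gene identifier in the RefSeq gene table of mouse assembly GRCm38.p6, and none of their symbols needed an update. That table was used for names and gene order only. The array annotation's build is not stated, so no coordinates are given. For a gene with several probe sets the one with the highest mean level was used, which left 22184 genes.

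The detection floor of each array was the 95th percentile of 1401 probe sets for olfactory and vomeronasal receptors, genes colon monocytes are not known to use: 3.26 in WT and 3.22 in Nlrp6-/-. A gene below the floor on 1 array was given as a bound, the other level against the floor or the gene's own value, whichever was higher. A gene above the floor on at least 1 array was counted if its difference or bound reached 2-fold. The receptor genes' own differences had an SD of 0.19, and 0 of 1391 reached 2-fold. Of the 422 genes with several probe sets above both floors, 30 had a probe set 2-fold apart, and in 22 of these all probe sets went in that direction. The 90th percentile of disagreement was 0.79. The single array per genotype limits the precision, and no test was run.

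The 43 gene lists, the floor, the thresholds, the rule for named genes and the alternatives were fixed before the data were examined. Per list, the median difference over members above the floor on at least 1 array was compared with 10000 random lists of the same size, drawn with matching on mean expression in 20 bins. A list with at least 5 measured members stood apart if its median fell in the highest or lowest 2.5%. These medians used the measured levels, not the bounds. This describes the arrays and is not a test, since genes are not replicates. Lists share members: Cxcl10 is both a chemokine and an interferon-gamma target, Il18 is in 3 lists and Fcgr1 is both a monocyte and a phagocytosis gene. Named genes were 8 chosen in advance, the 10 highest and 10 lowest differences above both floors, the 5 largest bounds in each direction, and in each list up to 4 members with the largest differences. The rule left out predicted genes, small RNAs and silent receptors from the highest and lowest genes, and it named any neighbour of Nlrp6 that was 2-fold apart. Genes named outside this rule, chosen after their values were seen, were Mt2, Epcam, Muc2, Tff3, Reg3b and Ctrl.

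Alternatives were subtraction of the median difference, renewed quantile normalization, subtraction of a loess curve of difference on mean level (span 0.3), other floors or none, the mean of a gene's probe sets, fold thresholds of 1.5 and 3, the mean of list members, and 10 bins. Removal of immunoglobulin genes and listed genes of other cell types, of members shared with their lists, or of H1f8 from the histone list, was added after the data were examined, as were lists of further epithelial, pancreatic acinar and NRF2 target genes. Intervals of differences between list medians came from 10000 bootstrap draws over genes.

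The scripts were tested on simulated arrays with the mean levels of all probe sets and the local spread of the single-symbol probe sets. Once changes were added, 9431 genes were above the floor on at least 1 simulated array. With no change, 21 genes were 2-fold apart. Of 50 genes changed 3-fold in each direction, 96% of the higher and 62% of the lower were recovered, and at 4-fold 100% and 70%. Fewer of the lower were recovered because a dim gene that falls meets the floor. The changed genes were drawn from those above both floors, so these shares do not measure a bias of the counts between directions. Unshifted lists of 20 genes landed in the outer tails in 4% of 400 draws. Lists shifted by 0.5 were found in 100% of 50 draws. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.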

Results

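Gene expression was measured in inflammatory monocytes sorted from the colon lamina propria of wild-type (WT) mice and of mice lacking Nlrp6, a NOD-like receptor of the inflammasome family. The mice had received azoxymethane (AOM), a colon carcinogen, at 10 mg/kg, and then 2% dextran sodium sulfate (DSS), which injures the colon epithelium, for 5 days from day 5. Cells were collected on day 10, during the acute colitis of this tumour model. The sort kept CD11b-positive cells with high Ly6C that lacked CD3, a T cell marker, and Ly6G, a neutrophil marker. Each genotype was represented by 1 Affymetrix Mouse Gene 2.1 ST array with 41345 probe sets. Levels ranged from 1.14 to 12.01 on the log2 scale in WT and from 1.14 to 12.34 in Nlrp6-/-. With 1 array per genotype there were no replicates, so no difference has an error or a p-value, and every difference below describes these 2 arrays.

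The comparison asks how loss of Nlrp6 alters the expression programme of colon inflammatory monocytes in this model. Type I interferon-stimulated genes were higher in Nlrp6-/- as a group: all 29 measured members lay above their WT level, with a median log2 difference of 0.98. Several monocyte-attracting chemokines were higher as well, including Ccl8 by 1.53, Ccl7 by 1.43 and Ccl2 by 1.32. Genes of the oxidative stress response were lower, among them Srxn1, which restores oxidised peroxiredoxins, at -1.36, and Gclc, a subunit of the enzyme that starts glutathione synthesis, at -1.31. Markers of epithelial, plasma, neutrophil and stromal cells were higher in the Nlrp6-/- sample too, while the monocyte markers had a median difference of -0.03. Tnf, the inflammatory cytokine, was at 9.23 in WT and 8.75 in Nlrp6-/-.

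Nlrp6 itself was below the detection floor on both arrays, at 2.32 in WT and 2.67 in Nlrp6-/-, against floors of 3.26 and 3.22. Its single probe set therefore gave no check of the genotype labels. Of 22184 genes with a probe set of their own, 9528 were above the floor on at least 1 array and 8566 on both. Levels on the 2 arrays correlated with Pearson's r = 0.977 across all probe sets, which are not independent replicates. Among genes above the floor on both arrays, 90.2% differed by less than 1.5-fold. Counting a gene below the floor on 1 array at its bound, 154 genes were at least 2-fold higher in Nlrp6-/- and 31 were at least 2-fold lower. Together these were 1.94% of the 9528 genes, and 83.2% of them were higher. Probe sets with no gene symbol had another balance: 305 were at least 2-fold higher and 367 lower, together 9.59% of the 7010 above the floor on at least 1 array. Arrays simulated with no change had 21 genes 2-fold apart. Their spread was taken from these same 2 arrays, so that number does not estimate how many genes would differ between samples of 1 genotype. With a stricter floor, at the 99th percentile of the silent receptor genes, the higher count was 93.

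**Figure D1:**
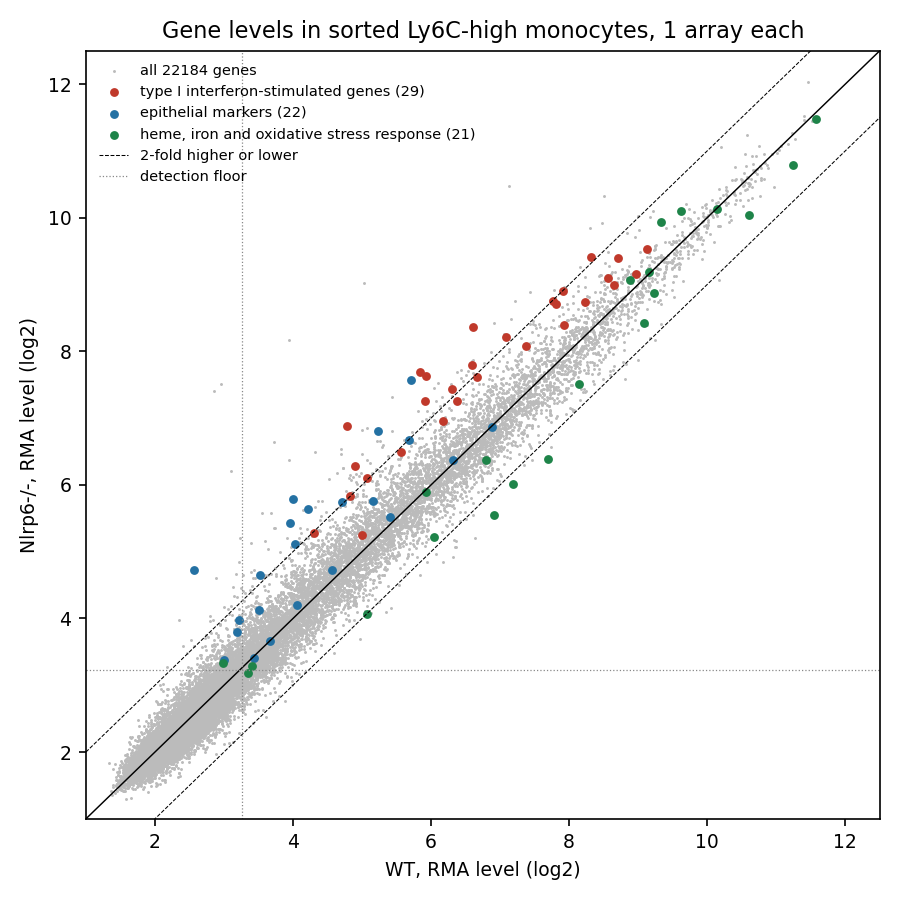
RMA level (log2) of each gene in WT monocytes on the x axis and in Nlrp6-/- monocytes on the y axis, 1 array each, with the measured members of 3 gene lists in colour, dashed lines at 2-fold and dotted lines at the detection floors. The 29 interferon-stimulated genes all lie above the diagonal, and 16 of the 21 heme, iron and oxidative stress genes lie below it.

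The largest differences above the floor on both arrays belonged to immunoglobulin variable segments, which encode the antigen-binding part of antibodies. Igkv9-124 was higher in Nlrp6-/- by 4.24 on the log2 scale, Ighv1-47 by 3.98 and Igkv4-91 by 3.35. Klk1, a tissue kallikrein, was higher by 2.92, Egln3, a hypoxia-induced prolyl hydroxylase, by 2.44, and Mitd1, a protein of the final step of cell division, by 2.17. The other 4 of the 10 highest were the interferon-induced genes Cmpk2 (2.10), Ifit1bl1 (2.03) and Ddx60 (1.89), and Lypd8 (1.87), which colon epithelium secretes. Of genes above the floor in Nlrp6-/- only, Igkv6-23 was at least 19.1-fold higher and Gdpd3, a lysophospholipase, at least 17.7-fold higher. Ctrb1, a digestive protease precursor of the pancreas, was at least 7.72-fold higher, Retnlg, a neutrophil product, at least 3.85-fold, and Sycn, a protein of pancreatic secretory granules, at least 3.00-fold.

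In the other direction, the lowest gene was the heme transporter Slc48a1, at -1.44, followed by Srxn1. Ikbkg, the regulatory subunit of the kinase complex that activates NF-kB, was at -1.32, and Gabarapl1, an autophagy protein, at -1.29. The Notch ligand Jag1 was at -1.26, as was Ttc39c, with Shtn1 at -1.30, Plekho2 at -1.23 and Pgap1 at -1.20. No gene seen above the floor in WT only reached 2-fold at its bound. The nearest were the histone gene H2bc3 at -0.82, Zf12 at -0.76, Fbxo40 at -0.75, Rps6kc1 at -0.69 and Pramel21 at -0.68.

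**Figure D2:**
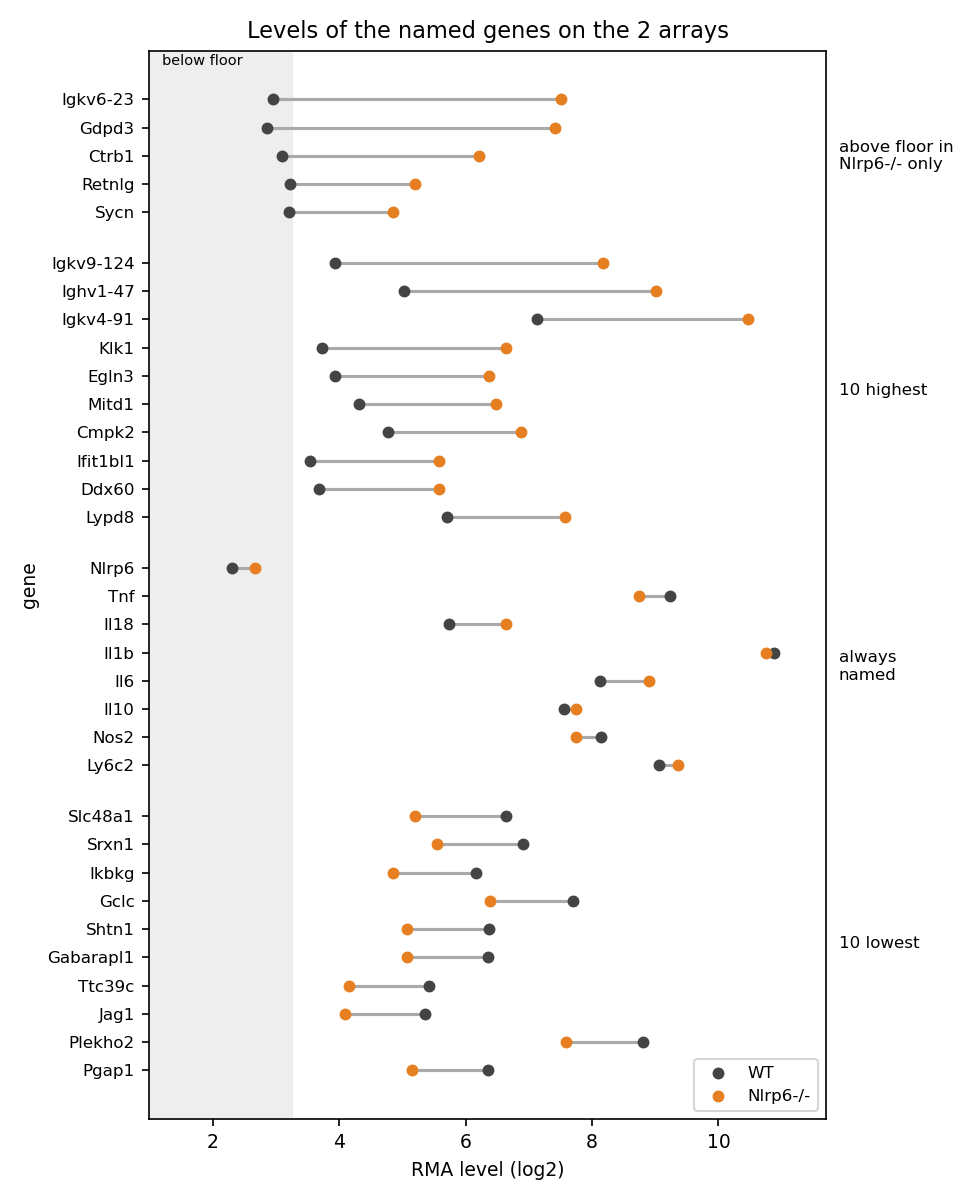
RMA level (log2) of the genes with the highest and lowest differences, of the always-named genes and of those above the floor in Nlrp6-/- only, with WT in grey, Nlrp6-/- in orange and the shaded range below the WT floor. Igkv6-23 and Gdpd3 go from below the floor to 7.52 and 7.41, and Nlrp6 stays in the shaded range on both arrays.

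Of the 29 measured type I interferon-stimulated genes, 22 were at least 1.5-fold higher and 12 at least 2-fold higher in Nlrp6-/-. The leading members were the mitochondrial nucleotide kinase Cmpk2, the ISG15 protease Usp18 (1.84), the antiviral effector Ifit1 (1.75) and the dynamin-like GTPase Mx2 (1.71). The list's median lay above all 10000 random lists matched on mean expression. The p200 and Ifitm genes, also induced by interferon, had a median of 0.35 at percentile 99.9, with Mndal higher by 1.04. Genes induced mainly by interferon-gamma had a median of 0.10 at percentile 89.8, within the range of matched lists. In that list Cxcl10, which type I interferon induces too, was at 8.16 in WT and 9.26 in Nlrp6-/-, Irgm2 was higher by 0.89 and Igtp by 0.68.

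Secreted cytokines had a median of 0.42, above all matched lists, with 16 of 19 members higher. Il15 was higher by 1.13, Il18 by 0.91, Csf3 by 0.88 and Il27 by 0.83. Il6 was at 8.13 in WT and 8.90 in Nlrp6-/-, a difference of 0.77, and Il10 differed by 0.19. Il1b, among the brightest genes, was at 10.88 and 10.75. Chemokines had a median of 0.32, exceeded by 0.02% of matched lists, and 7 of 21 were at least 2-fold higher, including Cxcl11 by 1.27. The TNF and NF-kB response genes had a median of -0.13 at percentile 5.70. None of the 21 members differed by 1.5-fold, although 18 were lower. Inflammasome sensors and effectors (median 0.17, percentile 95.2) and the IL-18 pathway (-0.08, percentile 29.0) were within the range of matched lists. Il18, in both, was at 5.73 in WT and 6.65 in Nlrp6-/-. Nos2, the inducible nitric oxide synthase, was at 8.14 and 7.75.

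Oxidative phosphorylation genes had a median of 0.34, above all matched lists, and 38 of 48 members were higher. The largest were subunits of the respiratory chain: Ndufa4 at 0.73, and Cox7b, Ndufa6 and Uqcrb at 0.69 each. Immediate early and heat-shock genes, which also respond to cell isolation, had a median of 0.33, with 22 of 28 members higher. The nuclear receptors Nr4a1 and Nr4a2 led this list at 1.15 and 0.83.

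The heme, iron and oxidative stress response had the lowest list median, -0.36, below all matched lists. Of its 21 members 16 were lower and 7 were at least 1.5-fold lower. The 4 at least 2-fold lower were Srxn1, Gclc, the biliverdin reductase Blvrb (-1.18) and the quinone reductase Nqo1 (-1.01). Lysosome and phagocytosis genes had a median of -0.21 at percentile 0.12, with the cholesterol exporter Npc1 at -0.68, the protease Ctsz at -0.62 and Hexa at -0.59. In the same list the Fc receptor gene Fcgr1 was higher by 0.88. MHC class II presentation had a median of -0.20 at percentile 1.26, with the peptide-loading chain H2-DMb1 at -0.73. That call ended without the filter on dim genes, at percentile 3.90, and with the stricter floor, at 2.83.

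**Figure D3:**
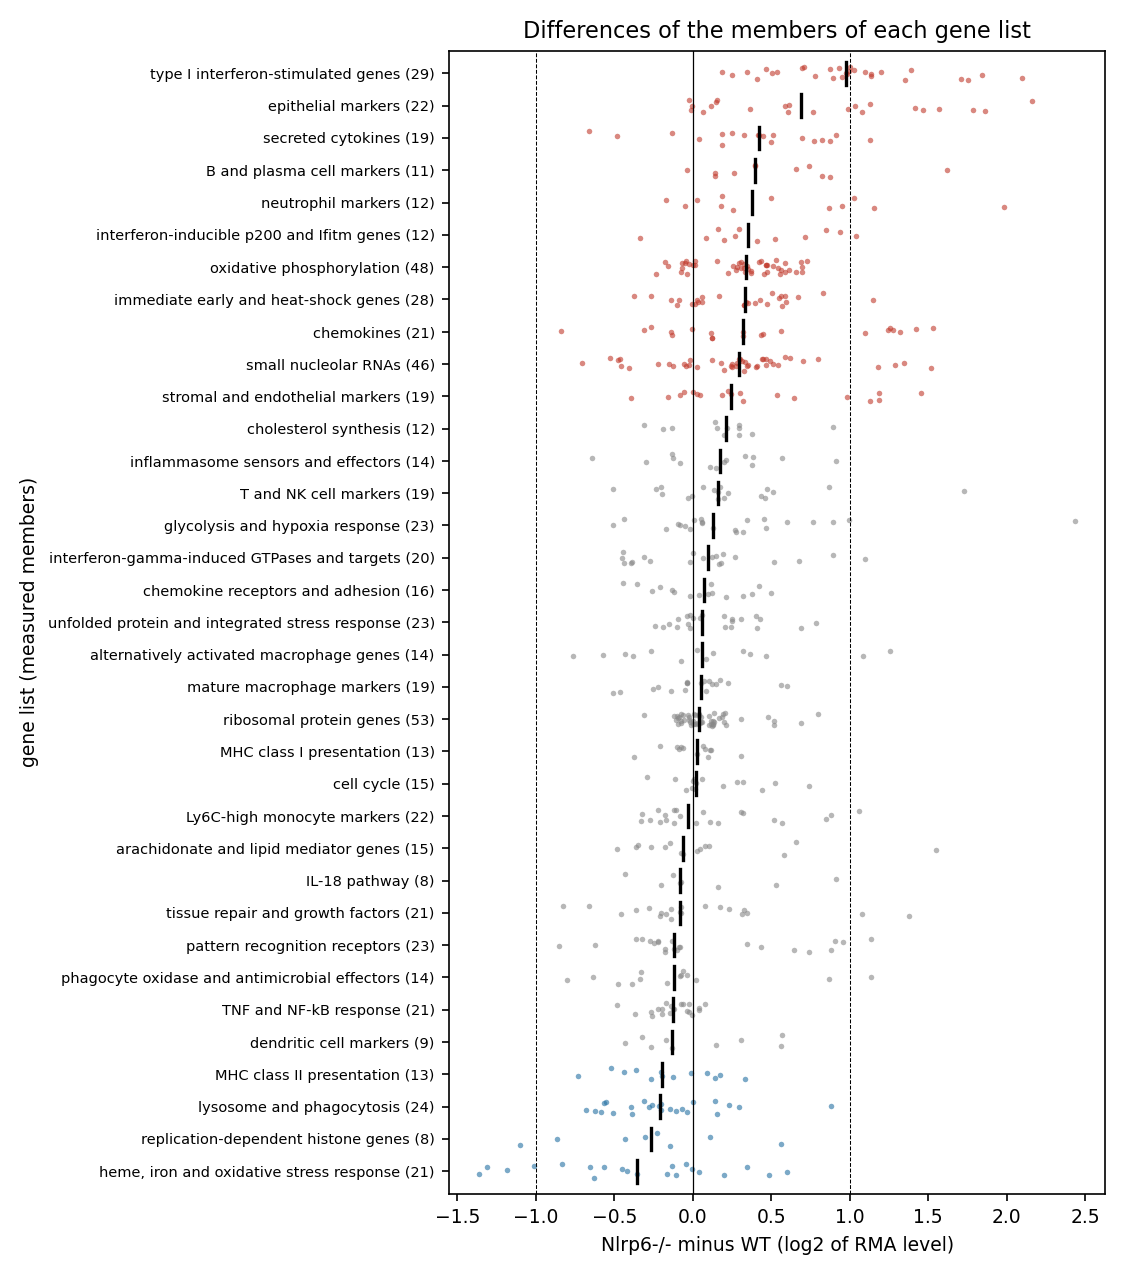
Log2 difference, Nlrp6-/- minus WT, of each measured member of the gene lists (points, with member numbers in brackets), the list median (black bar), and dashed lines at 2-fold, from 1 array per genotype. Lists in the highest 2.5% of matched random lists are red and those in the lowest 2.5% blue; microRNA, silent receptor and neighbour lists are not drawn. The interferon-stimulated genes have the highest median, 0.98, and the oxidative stress genes the lowest, -0.36.

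Monocyte identity genes did not stand apart, with a median of -0.03 at percentile 42.3. Ly6c2, which encodes the sorted surface antigen, was at 9.06 in WT and 9.36 in Nlrp6-/-, and F13a1, a coagulation factor subunit made by monocytes, was higher by 1.06. Mature macrophage markers had a median of 0.05. Markers of other cells differed more. Epithelial markers had a median of 0.69, above all matched lists, and 9 of 22 were at least 2-fold higher. They included Lypd8, Muc13 by 1.79 and Lgals4 by 1.57, and Zg16 at a bound of 1.47. The mucin Muc2 differed by 0.11, Tff3 by 0.15 and Reg3b by -0.01. B and plasma cell markers had a median of 0.40 at percentile 99.9, led by the plasma cell protein Mzb1 at 1.62. Neutrophil markers had a median of 0.38, with S100a8 higher by 1.16 and S100a9 by 1.03, both of which monocytes also express. With members required above the floor on both arrays, the neutrophil median was 0.19 at percentile 93.9. Stromal and endothelial markers had a median of 0.24 at percentile 98.9, with Mgp at 1.45 and Col1a2 at 1.19, and without the filter on dim genes they were at percentile 91.9. The size of these 4 shifts depended on the settings: without the filter on dim genes the medians were 0.26 (epithelial), 0.26 (B and plasma), 0.18 (neutrophil) and 0.10 (stromal), and with the stricter floor 1.06, 0.66, 0.53 and 0.59. T and NK markers (median 0.16, percentile 94.8) and dendritic cell markers (-0.13, percentile 14.5) were within the range of matched lists. T and NK markers passed the limit under 3 of 11 alternative settings. Of the 154 higher genes, 32 were immunoglobulin genes or members of the lists of other cell types, a grouping made after the data were examined. The 122 others still held genes typical of other cells that are in none of these lists, such as the pancreatic genes Ctrb1, Sycn and Ctrl.

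Of the 38 lists given a percentile, 11 stood apart on the high side and 5 on the low side. For lists of unrelated genes 1.9 would fall outside by chance. These lists share members and group related genes that can move together, so the counts are not a test against that number. Technical spread set a limit on single genes. For 422 genes with several probe sets above the floor on both arrays, the probe sets' differences disagreed by a median of 0.31.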

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

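The comparisons of epithelial with T and NK markers, of monocyte with oxidative stress genes and of other cells with the interferon pattern were chosen after the results were seen, as were the monocyte markers' own interval and the reading of the pancreatic list by its measured members.

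Probe sets outside the named comparison carried differences too. Of the 16010 with no gene symbol, 7010 were above the floor on at least 1 array. Of these, 305 were at least 2-fold higher in Nlrp6-/- and 367 at least 2-fold lower, 9.59% together against 1.94% of named genes, with extremes of at least 74.2-fold higher and at least 49.7-fold lower. Of the 1810 with several symbols, 24 were at least 2-fold higher and 3 lower. The genes behind them are not named here.

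The type I interferon-stimulated genes were higher in Nlrp6-/-, with a median of 0.98. A level-dependent bias between the arrays is argued against by the median differences in 5 bins of mean level, which ran from -0.02 to 0.04 among genes above both floors. The list median was 0.98 after a loess curve of difference on level was subtracted, still above all matched lists. That curve had little to remove, so the subtraction adds little. Cells other than monocytes cannot be told apart as a source, because 4 marker lists of other cell types (epithelial, stromal, B and plasma, neutrophil) were also on the high side. The gate for CD11b and Ly6C without CD3 and Ly6G should remove these cells, so such a source needs an incomplete sort or free RNA. The genotype, differences between individual mice and differences in the course of colitis stay open and untested with 1 array each.

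Markers of other cell types were higher in Nlrp6-/-. One form of a lower share of monocytes would raise every other type alike. Among members with a WT level under 6, the epithelial median exceeded the T and NK median by 0.71. The 95% bootstrap interval was 0.20 to 1.11, over 20 and 18 genes. For these members, this argues against an equal rise of both lists. The gap depended on the filter: without the filter on dim genes the list medians were 0.26 for 32 epithelial and 0.16 for 26 T and NK genes. Both were then on the high side, T and NK at percentile 99.2. The comparison cannot decide whether the share of monocytes was lower, since the sort itself removed CD3-positive cells. Epithelial RNA carried into the Nlrp6-/- sort may contribute: 18 epithelial genes not examined before had a median of 0.27 at percentile 99.8, and Epcam was at 4.71 in WT and 5.74 in Nlrp6-/-, but Muc2 (5.41 and 5.52) hardly differed. Pancreatic RNA stays open: 2 of 27 acinar genes not examined before were at least 2-fold higher, under the share set in advance as speaking against it. However, 18 were below the floor on both arrays, and the 9 measured had a median of 0.62, above all matched lists. With levels below a floor set to that floor, the median of the 9 was 0.41.

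Oxidative stress genes were lower in Nlrp6-/-, with a median of -0.36. After the loess curve was subtracted the median was -0.34, still below all matched lists, but that curve had little to remove. The median differences in bins of mean level, from -0.02 to 0.04, argue against a level-dependent bias. Dilution of monocyte RNA by other cells cannot be told apart: the monocyte markers' median was higher by 0.33, but the 95% bootstrap interval over genes, -0.04 to 0.73, held 0. Against dilution, 0 of 22 monocyte markers and 7 of 21 oxidative stress genes were at least 1.5-fold lower, and the monocyte median of -0.03 had an interval of -0.15 to 0.24. Going with dilution, 18 of 21 TNF and NF-kB response genes and 18 of 24 lysosome and phagocytosis genes were lower by any amount. The same held for only 11 of 22 monocyte markers and 6 of 13 MHC class I genes. These falls were small: 0 of the 21 and 3 of the 24 were at least 1.5-fold lower. The TNF and NF-kB median, at percentile 5.70, was within the range of matched lists. Lower expression of NRF2 targets is a candidate explanation, since 15 such genes not examined before had a median of -0.20 at percentile 1.40, with Abcc1 at -0.91 but Cbr1 at 0.81; whether this follows the genotype was not tested.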

How the results depend on the processing

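Removal of listed genes of other cell types, of members shared with their lists, or of H1f8 was chosen after the data were examined. The 154 higher and 31 lower genes depended on the thresholds: at 1.5-fold there were 592 higher and 291 lower, at 3-fold 29 and 0, and with the floor at the 99th percentile of the silent receptors 93 higher, where 4947 genes were compared instead of 9528. That floor also left 2 lists on the low side instead of 5. MHC class II genes were then at percentile 2.83 and microRNA genes at 3.05, just inside the limit. The histone list had too few measured members for a percentile. Under the 3 other normalizations the counts ranged from 148 to 163 higher and from 28 to 32 lower. Without immunoglobulin genes and the members of other cell types' lists there were 122 higher, Ctrb1, Sycn and Ctrl still among them, and 31 lower. Of the 11 lists on the high side 9 stood apart under every alternative fixed in advance, and of the 5 on the low side 2, the oxidative stress and lysosome lists. None of 152 values of named genes or 416 list values reversed a call. The silent receptors themselves, at percentile 2.87, entered the lowest 2.5% under 6 of 11 settings, so shifts of dim lists as small as theirs (-0.06) carry little weight. No paired analysis was possible because each genotype had 1 array and no test was run. Signal over background set a further limit, since 12656 genes were below the floor on both arrays and could show neither direction.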

Other observations

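The lists of further epithelial, pancreatic and NRF2 genes, the immunoglobulin counts and the histone list without H1f8 were chosen after the results were seen; the other lists below were planned.

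Of 19 measured immunoglobulin genes, 18 were higher in Nlrp6-/- and 10 at least 2-fold, with a median of 1.54. Only 21 immunoglobulin genes had a probe set of their own. Any segments on probe sets with no symbol or several are not covered, so the direction is not shown for the whole loci. Without the 4 variable segments named among the highest genes, 14 of 15 were higher and 6 at least 2-fold, with a median of 0.85. The pancreatic protease gene Ctrl was at 4.36 in WT and 5.76 in Nlrp6-/-, and Clps, the colipase gene, was higher by 1.30. Small nucleolar RNAs had a median of 0.30, above all matched lists, with Snord13 higher by 1.52 and Snora75 by 1.35. MicroRNA genes had a median of -0.11, below all matched lists, with Mir505 at -1.40 and Mir5099 at -1.11, but without the filter on dim genes they had a median of -0.03 at percentile 4.41 and with the stricter floor were at percentile 3.05. The histone list, matched by symbol, had a median of -0.27 at percentile 1.19. It took in H1f8 (-1.10), an oocyte linker histone that is not replication-dependent, and without it the list no longer stood apart, at -0.23 and percentile 3.47. With members required above both floors it was at percentile 2.55, and without the filter on dim genes it still stood apart, with a median of -0.14 at percentile 0.13.

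The remaining lists were within the range of matched lists. Some single members still differed. The cysteinyl leukotriene receptor gene Cysltr1 was higher by 1.55 in the arachidonate list (median -0.06), the growth factor gene Ereg by 1.38 in the tissue repair list (-0.08) and Arg1 by 1.08 among alternatively activated macrophage genes (0.06). Tlr7 was higher by 0.96 among pattern recognition receptors (-0.12), and the metal transporter gene Slc11a1 was at -0.80 among phagocyte oxidase and antimicrobial genes (-0.12). Glycolysis and hypoxia genes had a median of 0.13 at percentile 94.6 and passed the limit under 2 of 11 settings. Cholesterol synthesis (0.21, percentile 93.5) passed it under 1. Medians were 0.07 for chemokine receptors and adhesion, 0.03 for MHC class I, 0.02 for cell cycle, 0.06 for the unfolded protein response and 0.04 for ribosomal protein genes.

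The 40 measured neighbours of Nlrp6 in the gene order of GRCm38.p6 had a median of 0.10 at percentile 88.6, and none was 2-fold apart. Of these, 4 were at least 1.5-fold higher and 2 at least 1.5-fold lower. The largest differences were Ifitm5 at 0.94, Ifitm6 at 0.85, Irf7 at 0.78 and Krtap5-2 at a bound of 0.51. Ifitm5 and Ifitm6 are also in the p200 and Ifitm list, and Irf7 is in the type I interferon list. A link of these differences to the position near Nlrp6 was not tested. Gdpd3 lies 196 named genes from Nlrp6 on the same chromosome, and 60 measured neighbours of Gdpd3 had a median of 0.04. Lists with fewer than 5 measured members are given as values. Of eosinophil genes Prg2 was higher by 1.47, Ccr3 by 0.56 and Adgre4 by 0.21. Of mast cell genes Hdc differed by 0.25 and Kit by -0.02. Of platelet genes Pf4 was higher by 1.24, while Ppbp was at 3.74 in WT and below the floor in Nlrp6-/-, a bound of -0.52. Xist was at 9.93 in WT and 9.66 in Nlrp6-/-. Of strain-variable genes Glo1 was higher by 0.65, Nnt by 0.24 and Wdfy1 by 0.11. In the oxidative stress list the metallothionein gene Mt2 went against the median, at 0.60.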
